A study of Homo sapiens with 6 samples.

How the data were processed

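Total RNA from umbilical cord blood-derived megakaryocytes was labelled with biotin by the Affymetrix procedure, per the labels' protocols. The series held 6 samples, 3 treated with cortistatin A (CA) and 3 with DMSO for 96 h, and samples were grouped by the treatment given in their titles. A table of log2 values with 1 column per array was deposited by the authors; the array design, background correction and normalization behind it are not given in the sources used here. The values lay between 2.17 and 14.5 and the medians of the 6 arrays between 4.64 and 4.70, so the arrays had been brought to a common scale before deposit. Use of limma is recorded per the submitters' processing notes, with no version. The log2 scale was read from the values and from the authors' deposited table of results, whose log2 fold changes equal the difference of the group means of the value table. That table also holds limma p-values and adjusted p-values, moderated t and log-odds scores and gene positions in bases, per the file headers; every adjusted p-value listed by the authors was under 0.05 and every fold change at least 1.5-fold, so it holds changed probe sets alone. It lists 4349 probe sets, 2526 higher and 1823 lower in CA. An unpaired limma fit to all probe sets of the value table gave the same fold changes and the same adjusted p-values as the authors' deposited table to within rounding.

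Gene symbols were taken from the authors' deposited table: 3684 probe sets had 1 symbol, 166 had several and 499 had none, and 40 symbols were brought up to date with the RefSeq gene table. No name was taken from a probe set with several symbols. Probe sets outside that table are unnamed here. A gene without a symbol among the changed genes may therefore have no probe set, may have missed the threshold or the 1.5-fold limit, or may be unnamed, and counts adjusted over the list alone could not be had. The design fixed in advance called for 1 probe set per gene; because names covered changed probe sets alone, its written fallback of a test per probe set was used for the counts. Named genes were represented by their probe set with the highest mean over the 6 arrays. For 7 genes the named probe sets pointed in both directions: CD109, GPATCH2L, IP6K2, LNPEP, THBS1, TMEM30A and TNIK. Sex-linked genes that could identify a donor were not used. Some genes and control probe sets that the naming rule reached are not reported here.

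Differences were tested on the log2 scale with limma 3.58.1 (lmFit and eBayes, no trend, two-sided, R 4.3.3) with Benjamini-Hochberg adjustment over 54613 probe sets and a threshold of 0.05. The 62 control probe sets were left out of these counts and were fitted with all the others for the values given for them. No filter on dim probe sets and no further normalization was applied. The prior had 3.94 degrees of freedom and the residuals 4. Arrays carry no read depth, and their number limits the precision. A rank test of 3 against 3 arrays cannot go below an exact p of 0.1, so p-values come from the fit across probe sets.

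The choice of tests, alternatives and lists was made before the data were examined. From 36 gene lists, those with at least 5 named members were tested with limma's camera, with a preset correlation of 0.01 between genes, Benjamini-Hochberg adjustment over the lists tested and the 2721 named genes as the background. All of these genes had passed the threshold, so camera compared the changes of a list with those of other changed genes. A list's camera calls were also computed with an estimated correlation, and none of the 4 calls held with it. The genes named were the 15 largest increases and the 15 largest decreases past the threshold without overlap between the groups, up to 4 members of each list with the smallest p, and the named members of the Mediator kinase module, 143 genes in all; the largest changes left out open reading frame, uncharacterized, non-coding RNA, antisense and pseudogene symbols. Members named beyond these, where a count was small, were chosen after their values were seen.

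The alternatives were a replicate block, quantile normalization, centring on the median, leaving out dim probe sets, eBayes with trend and a robust prior, array weights, other probe set rules, leaving out each array, a log2 fold change of at least 1, an estimated correlation, and fry in place of camera. Chosen after seeing the data were a 1.5-fold limit, Fisher's exact test of direction and the 18S rRNA control signal as a covariate. The limma step was tested on simulated arrays of 54613 probe sets for this comparison, with 200 changed: it recovered 40.3% at a log2 change of 0.6, 94.0% at 1 and 100% at 2, with 6 false calls. In the data a far larger share, 11.3% of probe sets, was called. The adjusted threshold depends on that share, so these recovery rates do not carry over to the data. In simulated data of 2721 genes, camera gave a shifted set a p of 5.12e-47, an unshifted set 0.724 and a set mixed in direction 0.613. The simulated genes varied independently, so the preset correlation was not put to the test there. In the data the estimated correlation of the 4 called lists ran from 0.00891 (profibrotic) to 0.735 (G2/M). The profibrotic estimate lay under the preset 0.01, yet that list's unadjusted camera p went from 0.000156 to 0.019. The size of the correlation therefore does not account for the loss of that call, and the 2 settings differ in more than the correlation. Gene names were handled with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.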

Results

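Gene expression was measured on Affymetrix arrays in megakaryocytes, the platelet-producing cells, grown from umbilical cord blood. The cells had been treated for 96 h with cortistatin A (CA), an inhibitor of the Mediator-associated kinases CDK8 and CDK19, or with the solvent DMSO. Each treatment had 3 samples, with 1 array per sample. The deposited log2 values had medians between 4.64 and 4.70 on the 6 arrays. Pearson correlations across probe sets, which are not independent replicates, were 0.991 to 0.995 within a treatment and 0.975 to 0.983 between treatments. The labels do not say whether the samples of a treatment came from separate cultures or donors, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision of each value.

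The comparison of CA with DMSO asked what the compound did to the transcriptome of these cells at 96 h. Among genes with a symbol, 29 of 34 listed type I interferon genes, 12 of 24 TGF-beta response genes and 12 of 24 profibrotic mediators were higher in CA, and 6 of 38 mitotic genes were lower. By limma's camera these 4 lists stood apart from the other changed genes with a preset correlation, and none did with an estimated correlation (adjusted p from 0.437 to 0.538). COL1A1, which encodes a chain of type I collagen, had the largest measured increase, from a log2 level of 3.87 ± 0.51 (SD, n = 3) in DMSO to 10.4 ± 0.23 (SD, n = 3) in CA, a log2 fold change of 6.53 with SE 0.24 and a limma adjusted p of 1.42e-05. Its other probe sets with a symbol had 3.67 and 1.69, so the rank of COL1A1 rests on its brightest probe set. VNN1, which encodes the pantetheinase vanin, had the largest measured decrease, from 8.33 ± 0.66 to 4.33 ± 0.27, a log2 fold change of -4.00 with SE 0.30 and a limma adjusted p of 0.000327. This was its brightest probe set; the other VNN1 probe set with a symbol had -1.49, so its rank rests on the rule of the brightest probe set. Of 54613 probe sets tested, 3266 were higher in CA and 2886 were lower at a limma adjusted p under 0.05. At least a 2-fold change was found for 1249 higher and 559 lower probe sets, and at least an 8-fold change for 96 higher and 4 lower ones. Symbols were known for 2721 changed genes, of which 1638 rose and 1083 fell.

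The signal of ribosomal RNA, which is not a target of the labelling, also differed between the treatments. The 5' control probe set of 18S rRNA was higher in CA by a log2 difference of 2.38 with SE 0.55 and a limma adjusted p of 0.0296, with levels of 11.4 to 13.1 on the CA arrays and 9.52 to 11.2 on the DMSO arrays. With this signal as a covariate, a setting chosen after the values were seen, 226 probe sets were higher and 88 were lower, and the SE of the 6152 changed probe sets grew by a median factor of 1.82. Of the 143 genes named by the rule fixed in advance, 42 were still past the threshold in that fit and none changed direction. Without CA replicate 2, 1895 probe sets were higher and 1335 were lower; without CA replicate 1 these counts were 2058 and 1349, and without DMSO replicate 2 they were 1924 and 1475. Without DMSO replicate 3, 1885 probe sets were lower.

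**Figure D1:**
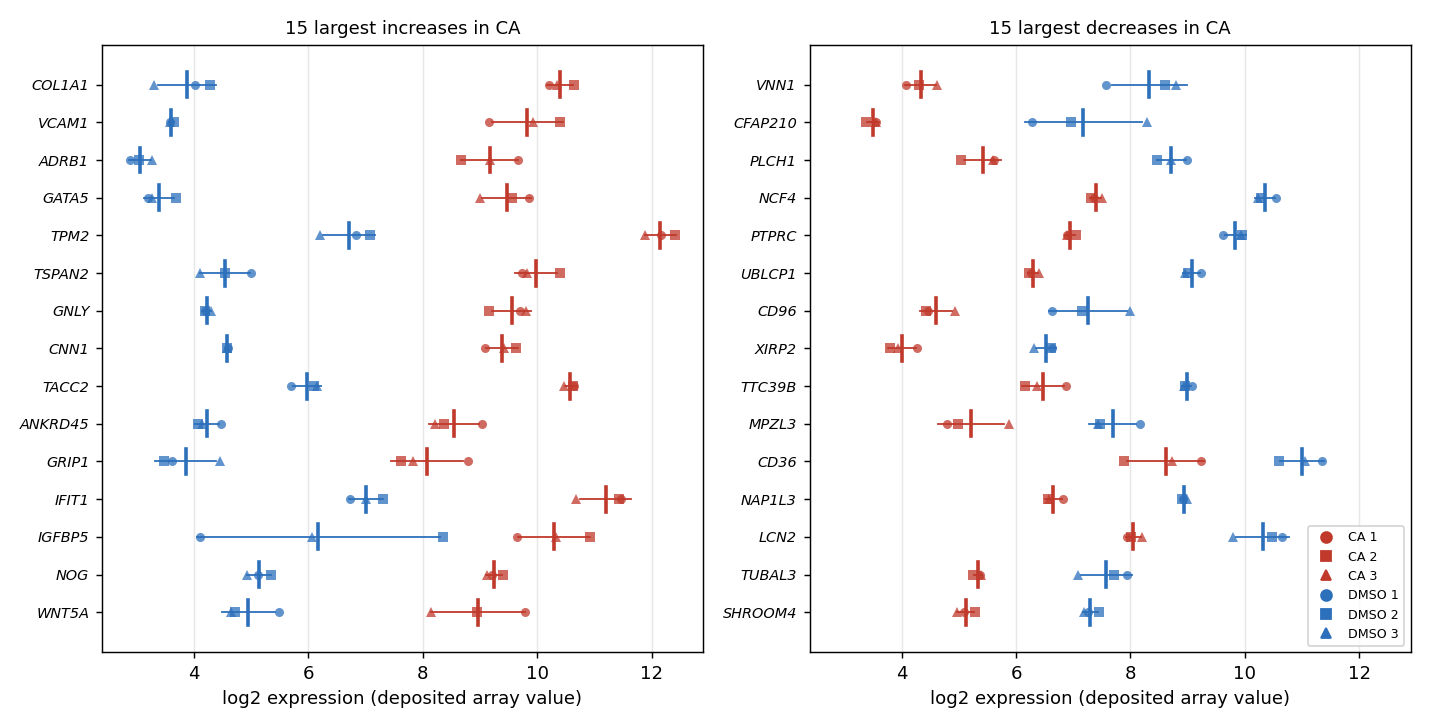
Log2 array values (horizontal axis) of the 15 genes with the largest increases (left) and the 15 with the largest decreases (right) in CA. Each symbol is 1 array, upright bars are means of 3 arrays and horizontal lines are ± 1 SD; COL1A1 lies at a mean of 10.4 in CA and 3.87 in DMSO, and the DMSO arrays of IGFBP5 are spread widely (SD 2.13).

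The 15 genes with the largest measured increases differed in function. VCAM1, an adhesion receptor for leukocytes, rose by a log2 fold change of 6.23. ADRB1, the beta-1 adrenergic receptor, rose by 6.12 and GATA5, a transcription factor of heart and endoderm development, by 6.09. The DMSO levels of COL1A1 (3.87), GRIP1 (3.85), VCAM1 (3.60), ADRB1 (3.06) and GATA5 (3.38) lay near the lower quartile of the arrays (3.51 to 3.56). Their fold changes therefore depend on probe background, and their order is not established. TPM2 (tropomyosin) and CNN1 (calponin), both known from smooth muscle, rose by 5.45 and 4.80. GNLY, the granule protein granulysin of cytotoxic lymphocytes, rose by 5.33, and the tetraspanin TSPAN2 by 5.44. NOG, a secreted BMP antagonist, and the WNT ligand WNT5A rose by 4.11 and 4.01. TACC2, ANKRD45 and GRIP1 rose by 4.60, 4.31 and 4.22, and the interferon-stimulated gene IFIT1 by 4.19. IGFBP5 was higher by 4.13 with SE 0.91 and an adjusted p of 0.0255, a call that was lost without CA replicate 1 (0.0594), CA replicate 2 (0.0946) or DMSO replicate 3 (0.0784). With the 18S signal as a covariate, 12 of the 15 largest increases were past the threshold. GRIP1 (3.26), IGFBP5 (4.55) and WNT5A (3.35) were not, at the log2 fold changes of that fit.

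COL1A1 (ENSG00000108821) had 3 probe sets in the authors' table of changed probe sets, all higher in CA, with log2 fold changes of 6.53, 3.67 and 1.69. The authors' deposited table places the gene on chromosome 17 from 50184101 to 50201632, with no genome build named in that table. Its positions overlapped the RefSeq positions of GRCh38 for 2716 of 2718 genes compared.

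Among the 15 largest decreases were several genes of leukocytes. PTPRC (the leukocyte phosphatase CD45), which had 3 named probe sets, all lower in CA, decreased by a log2 fold change of -2.89, from 9.83 ± 0.18 to 6.94 ± 0.09 (SD, n = 3). NCF4, a subunit of the phagocyte NADPH oxidase, had a log2 fold change of -2.97, and CD96, a receptor of T and NK cells, -2.66. CD36, a scavenger and thrombospondin receptor of platelets and monocytes, had -2.39 on the probe set with the highest mean, and its 4 named probe sets, which are changed ones by selection, were all lower. LCN2, the granulocyte protein lipocalin, had -2.26. CFAP210, PLCH1, UBLCP1, XIRP2, TTC39B, MPZL3, NAP1L3, TUBAL3 and SHROOM4 completed the set, with log2 fold changes from -3.68 for CFAP210 to -2.18 for SHROOM4. The CA level of CFAP210 (3.49) lay near the lower quartile of the arrays, so its fold change depends on probe background. In the fit with the 18S covariate CFAP210 had -4.77 and VNN1 -4.12, so the order of these 2 genes is not established. With the 18S signal as a covariate 10 of these 15 were past the threshold. CD96 (-3.04), MPZL3 (-1.49), CD36 (-2.39), LCN2 (-1.55) and TUBAL3 (-1.67) were not, at the log2 fold changes of that fit.

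Type I interferon response genes rose together. Of 34 genes in the list, 29 had a symbol among the changed genes, all 29 rose, and their median log2 fold change was 1.78. IFIT1, an RNA-binding antiviral protein, rose by 4.19, from 7.01 ± 0.29 to 11.2 ± 0.45 (SD, n = 3). The GTPase MX1 rose by 3.54, IFIT3 by 2.35 and the ISG15 ligase HERC5 by 1.89. The list stood above the other named genes by limma's camera (adjusted p = 6.18e-05 with a preset correlation of 0.01; adjusted p = 0.538 with an estimated correlation). In the list of interferon gamma response genes, 7 rose and 1 fell of 25, with CXCL11 at a log2 fold change of 3.42, the peptide transporter TAP1 at 1.73 and CXCL10 at 1.40, and this list did not pass camera (adjusted p = 0.123). The 18S control signal moved with these genes, and with it as a covariate the type I list had an adjusted p of 0.000147. Over the alternatives run with camera its adjusted p lay between 1.17e-05 and 0.65. In the fit with the 18S covariate TAP1 (1.64) and CXCL10 (0.96) lost their calls, at the log2 fold changes of that fit.

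TGF-beta response genes rose as well, 12 of 24 listed, with no listed gene among those that fell and a median log2 fold change of 1.62. After COL1A1, the matricellular protein CCN2 rose by 3.44 and the repressor TGIF1 by 1.63. THBS1 was counted as rising by the rule of the brightest probe set, but 3 of its named probe sets were higher and 1 was lower. The list passed camera (adjusted p = 0.00793; adjusted p = 0.538 with an estimated correlation). Of 24 profibrotic mediators and matrix enzymes, 12 rose and none fell, with a median of 2.31. CCN1 rose by 3.80, from 5.71 ± 0.25 to 9.51 ± 0.11 (SD, n = 3), the lysyl oxidase LOXL3 by 2.59 and the growth factor PDGFB by 2.04. Camera gave an adjusted p of 0.0018 for this list (adjusted p = 0.437 with an estimated correlation). Its estimated correlation, 0.00891, lay under the preset 0.01, so correlation between its genes does not account for this loss. CCN2 belonged to both lists, and S100A8 and S100A9 were shared with the granulocyte markers. With the 18S covariate the adjusted p was 0.00696 for the TGF-beta list and 0.000113 for the profibrotic list. Over the alternatives run with camera the adjusted p lay between 0.00413 and 0.65 for the TGF-beta list and between 0.000113 and 0.65 for the profibrotic list. In the fit with the 18S covariate TGIF1 (1.71) and S100A9 (1.23) lost their calls, at the log2 fold changes of that fit.

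With camera's preset correlation, mitotic genes were the only list that stood below the other named genes (adjusted p = 0.0364), and this call was lost with an estimated correlation (adjusted p = 0.538). Of 38 G2/M genes 6 fell and none rose: the kinetochore genes NUF2 (-0.95) and NDC80 (-0.88), ECT2 (-0.93), the proliferation marker MKI67 (-0.87), ASPM (-0.87) and TOP2A (-0.75). The other 32 had no symbol among the changed genes. The list's adjusted p was also above 0.05 without CA replicate 3 (0.0546), without DMSO replicate 1 (0.0516) and with the 18S covariate (0.113), in a range from 0.0196 to 0.65 over the alternatives run with camera. NDC80 and MKI67 each lost their own call without CA replicate 2 (0.0817 and 0.0591), and NDC80 also without CA replicate 1 (0.0673) and DMSO replicate 2 (0.0593). Of 35 G1/S and replication genes, 2 fell, among them MCM5 (-0.66), and CCNE1 rose (0.59). Of 16 CDK inhibitors and G1 cyclins, CCND2 (1.66) and CCND1 (1.65) rose and CDKN2A (-0.96) fell. MCM5, CCNE1 and CDKN2A did not keep their calls when single arrays were left out. In the fit with the 18S covariate CCND1 and CCND2 were past the threshold. NUF2 (-0.86), NDC80 (-0.59), ECT2 (-1.16), MKI67 (-0.59), MCM5 (-0.19), CCNE1 (0.64) and CDKN2A (-0.92) were not, at the log2 fold changes of that fit.

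**Figure D2:**
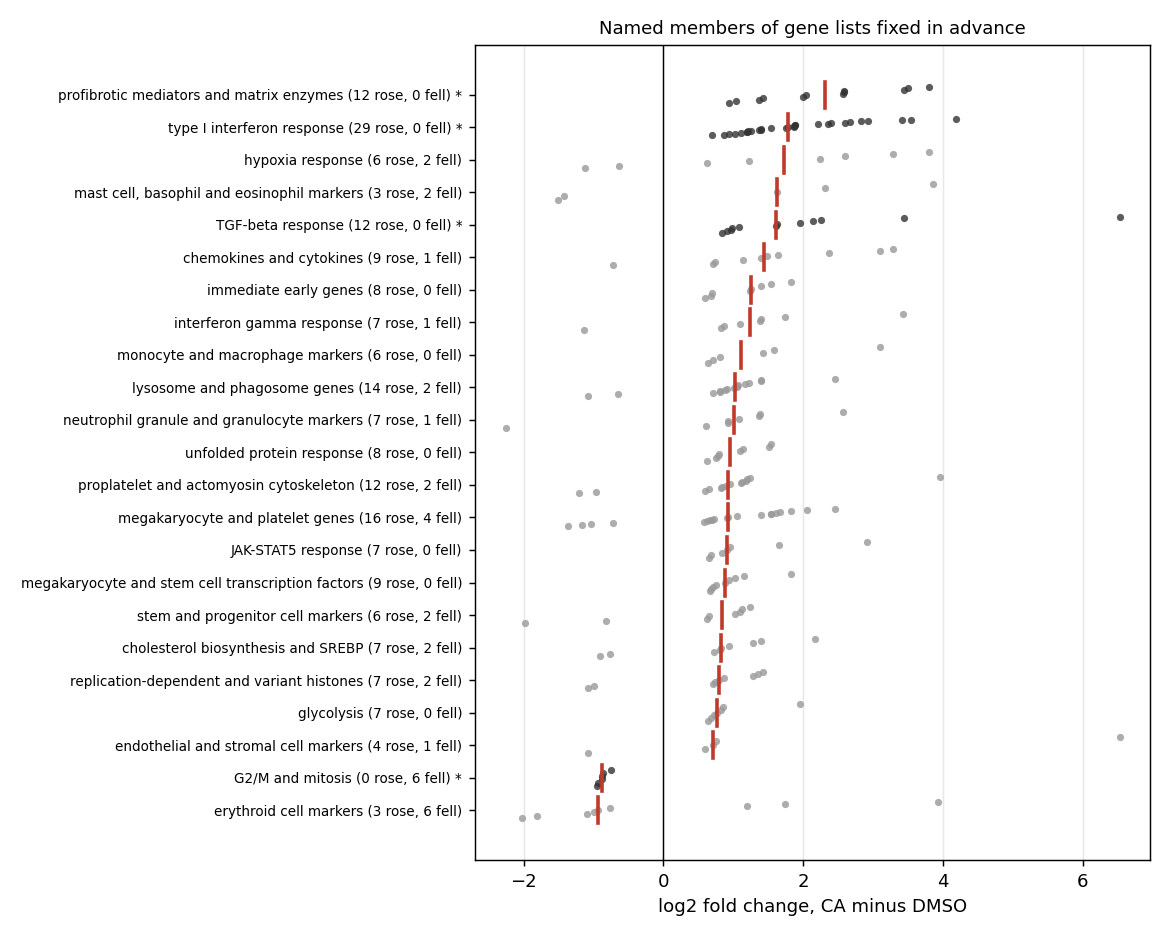
Log2 fold changes (CA minus DMSO, horizontal axis) of the members of each gene list that had a symbol among the changed genes, for lists with at least 5 such members. Each point is 1 gene, red bars are list medians, and dark points with an asterisk mark the 4 lists past an adjusted p of 0.05 by camera with a preset correlation, none of which was past it with an estimated correlation; all 29 type I interferon genes lie above 0 and all 6 G2/M genes below it.

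Genes of the megakaryocyte lineage changed mostly upward without the lists passing camera, where 60.2% of all named genes rose. Of 42 megakaryocyte and platelet genes 16 rose and 4 fell, with a median log2 fold change of 0.92 (adjusted p = 0.172). VWF, the platelet adhesion protein, rose by 2.45, from 10.3 ± 0.34 to 12.8 ± 0.26 (SD, n = 3), ITGB3 (integrin beta-3) by 1.54 and GP5 (glycoprotein V) by 1.54. F13A1, the A chain of factor XIII, had a log2 fold change of -1.16. Of 20 megakaryocyte and stem cell transcription factors 9 rose and none fell (adjusted p = 0.0974), among them ETS1 (1.82), LMO2 (0.88) and RUNX1 (0.75). Of 24 cytoskeletal genes 12 rose and 2 fell (adjusted p = 0.107), with MYL9 (myosin regulatory light chain) at 3.96, TUBA8 at 1.24, ZYX at 1.20 and TUBA4A at 1.11. Of the 7 genes of the Mediator kinase module, which holds the targets of the compound, only MED12L had a symbol among the changed genes, and it rose by 1.28 with SE 0.17. With the 18S covariate MYL9 alone of the genes given here was past the threshold; MED12L was at 0.72 (adjusted p = 0.239) and VWF at 2.24 (adjusted p = 0.0594).

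Signalling and metabolic lists also had more rising than falling members, as did all named genes together, of which 60.2% rose. Among 37 chemokines and cytokines 9 rose and 1 fell (adjusted p = 0.0974), led by the angiogenic factor VEGFA (3.29) and CCL8 (3.10). All 7 named of 18 JAK-STAT5 genes rose (adjusted p = 0.103), with SOCS3, a feedback inhibitor of JAK signalling, at 2.90 and STAT5A at 0.68. All 8 named of 24 immediate early genes rose (adjusted p = 0.103), with KLF4 at 1.82 and ATF3 at 1.53. All 8 named of 23 unfolded protein response genes rose (adjusted p = 0.103), with TRIB3 at 1.51. In the lysosome list 14 rose and 2 fell of 27 (adjusted p = 0.103), with GPNMB at 2.45 and the protease LGMN at 1.40. Of 22 hypoxia genes 6 rose and 2 fell (adjusted p = 0.23), with ADM at 3.79 and DDIT4 at 2.60. Of 22 glycolysis genes 7 rose and none fell (adjusted p = 0.126), with PKM at 1.95. Of 31 cholesterol genes 7 rose and 2 fell (adjusted p = 0.302), with SCD at 1.39. Of 25 histone genes 7 rose and 2 fell (adjusted p = 0.474), with H2AC8 at 1.42 and H3-3B at -1.07. Among these genes SOCS3, ADM and PKM were past the threshold with the 18S covariate, and the others were not.

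Lists with fewer than 5 named members were not tested. Of 16 myeloid transcription factors 4 rose and none fell, among them KLF4, CEBPD and IRF8, and IRF8 lost its call when single arrays were left out. IL1B, CCL2, TNFAIP3 and CYLD rose among 26 NF-kappaB genes, ABCG1, PLTP and MYLIP among 11 LXR genes, MDM2, GADD45A and FDXR among 26 p53 genes, and TNFRSF19, CCND1, MYC and DKK1 among 14 WNT targets. DKC1, MYC and TFRC rose among 28 ribosome biogenesis genes. Of 38 oxidative phosphorylation genes 1 rose and 1, UQCRB, fell, and of 11 MHC class II genes HLA-DPA1 fell by a log2 fold change of -0.85. TNFAIP3, CYLD, ABCG1, FDXR, MYC, DKK1 and TFRC each lost their call without at least 1 array. Of the genes followed, CEBPD, TNFRSF19 and CCND1 were past the threshold with the 18S covariate, and the others were not.

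Markers of other blood cells moved in different directions. Of 29 erythroid markers 3 rose and 6 fell (median log2 fold change -0.94, mean -0.09; camera adjusted p = 0.209); the membrane protein gene EPB42 rose by 3.93 while GYPB (-1.81) and KLF1 (-1.10) fell. Of 23 granulocyte markers 7 rose and 1 fell (adjusted p = 0.182), with S100A8 at 2.57 and ELANE at 1.08. Of 28 monocyte and macrophage markers 6 rose and none fell (adjusted p = 0.105), with MRC1 at 1.58 and CD14 at 0.63, from low DMSO levels of 3.95 and 3.69. Mast cell markers were divided (3 rose and 2 fell of 23; adjusted p = 0.682), with HPGDS at 3.86 and KIT at -1.43. Of 25 stem and progenitor markers 6 rose and 2 fell (adjusted p = 0.544), with CD34 at 1.02 and GUCY1A1 at -1.99. Of 16 endothelial and stromal markers 4 rose and 1 fell (adjusted p = 0.364), with PECAM1 at 0.75, ACTA2 at 0.71 and TEK at -1.07. IRF4 and IRF8 rose among 21 dendritic markers, and GNLY, IGLL1, IL7R and NKG7 among 23 lymphocyte markers; the calls of IRF4, NKG7 and TEK were lost without at least 1 array. In the fit with the 18S covariate EPB42, S100A8, HPGDS and GNLY were past the threshold, and the other markers given here were not.

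**Figure D3:**
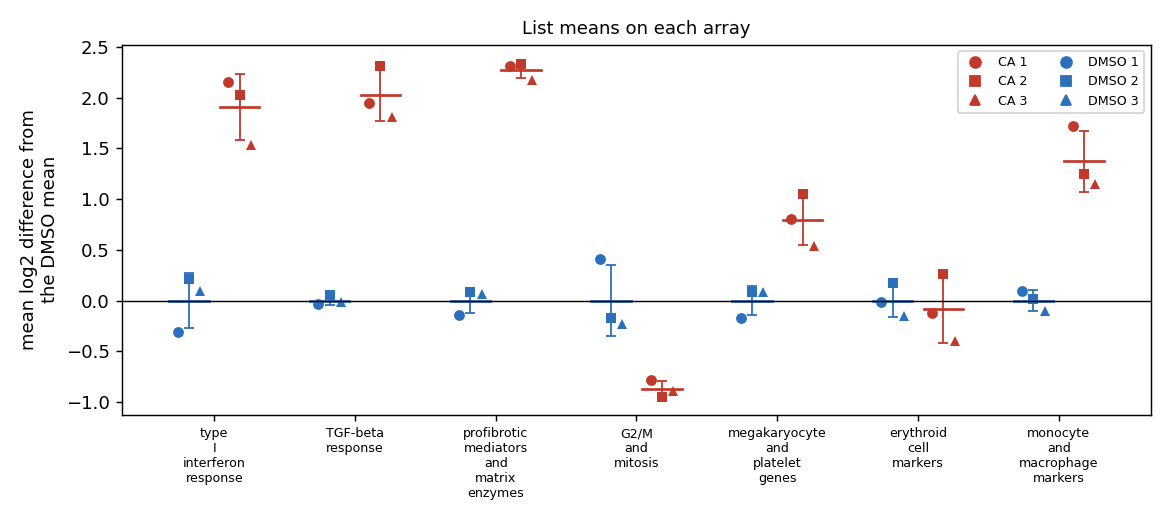
Mean log2 difference from the DMSO mean (vertical axis) of the named members of 7 gene lists on each array. Symbols are arrays, horizontal bars are means of 3 arrays and error bars are ± 1 SD; the type I interferon mean was 2.16, 2.03 and 1.54 on CA arrays 1, 2 and 3, and the G2/M mean was 0.40 on DMSO array 1 against -0.18 and -0.23 on the other DMSO arrays.

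CA replicate 3 stood closer to the DMSO arrays than CA replicates 1 and 2. On the first principal component, which held 66.4% of the variance, it lay at -30.6 against -56.8 and -60.0, with the DMSO arrays between 47.6 and 51.3. Without it, 4380 probe sets were higher and 3800 were lower in CA. Its actin 3' minus 5' control difference was 1.86 log2 units, against 1.32 and 0.97 on the other CA arrays and 1.52 to 1.80 on the DMSO arrays.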

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

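The tests of explanations here were chosen after the patterns had been seen; for the 18S covariate alone the bounds were set before its result was known. Of 6 control probe sets of ribosomal RNA, which the comparison of genes left out, 4 passed the threshold with signals above the DMSO level on all 3 CA arrays. For 18S rRNA the log2 differences were 1.18 at the 3' end, 2.38 at the 5' end and 1.68 in the middle, and for 28S rRNA 1.43 at the 5' end. The 28S probe sets in the middle (0.52, adjusted p = 0.0582) and at the 3' end (0.11, adjusted p = 0.602) did not pass.

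The 6152 changed probe sets could in part reflect RNA or labelling quality, since the rRNA signal moved with treatment. With the 18S signal as a covariate, 308 of the 6152 (5.01%) stayed past the threshold in the same direction, which lies at the bound of 5% set for rRNA as the cause. The SE of the 6152 grew by a median factor of 1.82, while probe sets changed at least 2-fold kept a median of 0.83 of their change. By limma no probe set had an 18S slope past the adjusted threshold, and 4296 (7.87%) had a slope at an unadjusted p under 0.05, so a loss of precision and an rRNA effect cannot be told apart. The 18S signal of DMSO replicate 3 lay 0.453 of the way to CA replicates 1 and 2. Its response score was 0.0424, on a scale from 0 in the other DMSO arrays to 1 in CA replicates 1 and 2. CA replicate 3 had a score of 0.750 at an 18S 5' signal of 11.4, against 11.2 on DMSO replicate 3. These arrays had unlike scores at similar 18S signals, but 1 array of each treatment excludes nothing. A lower share of megakaryocytes was not decided. Of named monocyte and granulocyte markers 13 of 14 rose, while 6 of 9 erythroid markers fell (Fisher's exact test, two-sided, p = 0.00494). That test takes genes of the same arrays as independent and does not measure the megakaryocyte share. No general fall of megakaryocyte genes was seen: 16 of 20 named ones rose, against 60.2% of all named genes. Their list did not pass camera (adjusted p = 0.172). More monocytes or granulocytes stay open: PTPRC, TYROBP, AIF1 and NCF4, abundant in those cells, had a median log2 fold change of -2.45, but their DMSO levels (9.83, 9.55, 11.5 and 10.4) were high enough for another cell type to have supplied them; an effect of CA itself stays open as well.

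CA replicate 3 showed a smaller change than CA replicates 1 and 2, with a median ratio of 0.717 over 1571 rising and 0.637 over 818 falling probe sets. These probe sets were picked by their change in CA replicates 1 and 2, so part of the shortfall follows from that choice. With probe sets chosen without the array scored, the response scores of CA replicates 1 and 2 were 0.923 and 0.949, and that of CA replicate 3 was 0.750. Over the same probe sets, an admixture of untreated RNA called for unlike shares, 41.3% by rising and 26.1% by falling ones. The share from rising ones left falling ones at a median difference of -0.213 log2 units from the predicted level (95% bootstrap interval -0.267 to -0.162). That interval resampled probe sets of this 1 array, which are not independent, and holds no spread between arrays. The prediction also assumed mixing on the linear scale of the array values, so admixture is not excluded. RNA quality could not be excluded. The response score changed by 0.00541 per log2 unit of the actin 3' minus 5' difference within DMSO, with an interval half-width of 1.11. Between the CA arrays it changed by -0.232. DMSO arrays hold no response to CA that poor RNA could weaken, so a slope within DMSO cannot decide this at any precision. The amount of labelled target stays open in the same way, with -0.039 per log2 unit of spike-in signal within DMSO, a half-width of 2.28, and -0.287 between the CA arrays. A weaker response in that sample was not tested.

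COL1A1 and 8 of 10 contractile or actomyosin genes, picked after their values were seen and without an enrichment test, were higher in CA. CALD1 (-0.65) and the non-muscle myosin gene MYH10 (-0.97) were lower. Cross-hybridization of a single COL1A1 probe set is argued against, since another probe set named COL1A1 rose by a log2 fold change of 3.67 with an adjusted p of 0.000127. A probe set of this gene that did not change would be unnamed here, and cross-hybridization shared by several probe sets was not tested. Stromal cells in the CA cultures could not be excluded: of 8 stromal markers, 2 had a symbol among the changed genes, COL1A1 and ACTA2, and the smaller rise was 0.711 for ACTA2. The other 6 are unnamed here, which keeps this open, and induction by CA in the megakaryocytes stays open too.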

How the results depend on the processing

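The 1.5-fold limit, Fisher's exact test and the 18S covariate were chosen after seeing the data. Counts of higher and lower probe sets stayed within 1.5 times their values (3266 and 2886) under quantile normalization, median centring, the dim filter, trend with a robust prior and array weights, and so did the 3 lists up and 1 down there and with other probe set rules. Leaving out single arrays gave 1895 to 4380 higher and 1335 to 3800 lower probe sets, 3 lists up, and 0 to 1 list down, with 0 without CA replicate 3 or DMSO replicate 1; fewer arrays were fitted, and the cause was otherwise not tested. A log2 fold change of at least 1 gave 1249 and 559, and the 1.5-fold limit gave 2523 and 1825, by construction. The 18S covariate gave 226 and 88, with 3 lists up and 0 down; loss of precision and an rRNA effect as its cause cannot be told apart. By camera, an estimated correlation gave 0 lists up and 0 down, alone and together with the replicate block, and alone 1 list, the profibrotic one, had an unadjusted p under 0.05 (0.019); fry gave 21 up and 1 down, but it does not compare a list with other genes and ran on members already past the threshold. Fisher's exact test gave 3 and 1. The replicate block gave 3603 higher and 3097 lower probe sets, 5550 of them shared with the unblocked calls, and 3 lists up and 1 down; samples of the same number had deviations correlated at 0.34, 0.04 and 0.02, and only number 1 had its best partner in its own number, so the numbers were not taken to pair samples. Of the 143 genes named, the block ended 1 call (MCM5), trend with a robust prior 1 (IGFBP5), the mean of probe sets 1 (FDXR), single arrays 1 to 18 and the 18S covariate 101, and none was reversed; the dim filter removed 9. Of the 10 splits of the 6 arrays, 1 gave as many calls as the real 6152 (itself) and the highest other gave 0. At an unadjusted p under 0.05 the others gave at most 4375, against 13194. Each other split put arrays of both treatments in both groups, so the treatment difference widened the spread within groups. Few calls were therefore to be had from them, and 10 splits are too few for a share under 0.05. Signal near background limits genes with log2 levels near the lower quartile of about 3.5.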

Other observations

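The gene groups in this part were put together after their values had been seen, and no enrichment was tested. Some contractile genes known from smooth and cardiac muscle were among the strongest increases, among them TPM2, CNN1 and MYL9. MYH11 (smooth muscle myosin) rose by a log2 fold change of 3.77 on the brightest of its 4 named probe sets. KCNMB1 rose by 3.71, MYL4 by 3.56, TNNI3 by 2.78 and ACTG2 by 2.17. TPM1 (1.18) and ACTA2 (0.71) rose less, and the cytoskeleton list fixed in advance did not pass camera (adjusted p = 0.107). Not every related gene rose: CALD1 had -0.65 and the non-muscle myosin gene MYH10 -0.97. Some secreted signalling factors rose too, with INHBA at 3.62 and GDF15 at 3.37, beside NOG and WNT5A. In the chemokine and cytokine list 9 rose and 1, IL18, fell (-0.72), and that list did not pass camera (adjusted p = 0.0974).

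A set of 5 genes of inflammasome and inflammatory caspase signalling fell, while of the inflammasome substrates IL1B rose by 1.48 and IL18 had -0.72. CARD16 had a log2 fold change of -2.07, CASP4 -1.44, PYCARD (the ASC adaptor) -1.38, CARD6 -1.33 and CARD8 -0.66. Of the HLA class I genes, 4 are given here, which rose, with HLA-B at 2.00, HLA-F at 1.62, HLA-G at 1.54 and HLA-E at 1.27. Their probe sets may share signal between these related genes. The metallothioneins MT1X, MT1H, MT1G, MT2A and MT1F rose by 1.32, 0.95, 0.74, 0.73 and 0.65. Beside PTPRC and NCF4, 3 other genes of leukocytes fell, with TYROBP from a level of 9.55 to 7.55, AIF1 at -1.99 on the brightest of 3 named probe sets and DOCK2 at -1.62. Other leukocyte genes rose, among them GNLY, IL7R, CTSG (1.38) and FGL2 (3.10).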
